A study of Mus musculus with 10 samples.

How the data were processed

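Poly-A selected RNA from 10 samples of cultured mouse primary mammary epithelial cells was sequenced, 5 with biglycan protein at 100 ng/mL and 5 without. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase and purified on a column, and libraries were made with the NEBNext Ultra kit. The deposited values are raw whole-number read counts per gene symbol, 1 column per sample. The submitters' processing notes name FastQC, cutadapt 1.9.1, HISAT2 2.2.1, HTSeq, DESeq2 and the genome build GRCm39; the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping or antisense genes, and of genes with near-identical copies, may therefore not be separable. The reference annotation at hand was of another build, so no coordinates are given, and it served only for transcript length and GC content by gene symbol.

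Groups and replicate numbers came from the sample titles, and the count columns carry the names in the sample descriptions. Totals ranged from 18292624 to 21820560 counts. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom over genes with a mean of at least 50 counts was 2.43 to 18.1 within groups and 3.66 to 20.8 between groups, so none was treated as a repeat deposit of the same library. This does not show that they came from separate cultures or animals. The design, the alternatives, the 44 gene lists and the rule for naming genes were fixed before the data were examined. The 2 alternatives added later, and the tests of explanations, were chosen after exploratory runs on these data.

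Genes were kept by edgeR's filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with robust estimation, with treatment as the single term and Benjamini-Hochberg adjustment over 14415 genes; an adjusted p under 0.05 was a call. Fold changes are BGN over Control. The SE was taken from the log2 fold change and its F statistic, and the 95% interval from that SE. CPM values are counts scaled to a common library total with TMM factors, except the sums over markers of other cell types, which were scaled by library totals alone. The biological coefficient of variation was 6.85%. Lists with at least 5 tested members, 38 of 44, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01; the estimated correlation and fry, which tests whether a list's genes move on balance one way, stand beside it. A list's deviation per library is the mean over its genes of the log2 CPM minus the gene's mean over the 10 libraries. Single values were compared by the exact permutation test over 252 assignments, whose smallest p is 0.00794.

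Named genes were fixed by rule. Part (a), the 10 largest rises and falls among called genes, was empty. Part (b) was up to 4 members of smallest p in each list, of which the text gives 4 for WNT targets and receptors and 2 for the other WNT, biglycan, migration and matrix lists and for the called lists; 1 gene that this part names is not reported here. Part (c) was Bgn, Axin2, Lef1, Lgr5, Ccnd1, Myc, Tlr2, Tlr4, Vim and Cdh1. Part (d), used because no gene passed, was the 10 genes of smallest p with a mean of at least 50 counts.

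The steps were tested on simulated data drawn from the gene means, dispersions and library sizes of this comparison, over 14415 genes with 50 changed at each fold. The changed genes were drawn only from those with a mean of at least 50 counts, so detection of rarer genes was not tried. The rates hold for this number and mix of changed genes and may be lower where fewer genes change. The edgeR step called 78% of genes changed 1.25-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold or 3-fold, and 13 of 14215 unchanged genes. With no change 0 of 38 lists were called by camera, and the WNT target list raised 1.2-fold was called. Simulated genes were independent of each other, which real genes are not. Alternatives were other scalings (DESeq2 size factors, upper-quartile factors, library totals), no or a stricter filter (CPM of at least 1 in at least 5 libraries), DESeq2 1.42.0, limma-voom with quality weights, no robust estimation, the replicate number as a block, 1 surrogate variable (sva 3.50.0), stricter thresholds and leaving out each library. The 2 added later were leaving out BGN replicate 5 and Control replicate 5 together, and removing each library's trend on transcript length and GC content, which were known for 97.7% of tested genes. List medians given before and after this removal are of the difference between group means of log2 CPM. They are not edgeR log2 fold changes and so differ slightly from the other medians given.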

Results

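RNA was sequenced from primary epithelial cells isolated from the mouse mammary gland and kept in culture. In the BGN group, 5 samples received biglycan protein (BGN), a small leucine-rich proteoglycan of the extracellular matrix, at 100 ng/mL. The Control group held 5 samples without added protein. The comparison asked which transcripts respond to soluble biglycan, with WNT signalling, the pathway through which beta-catenin controls transcription, named as the focus, and with epithelial migration as the wider question. Between 18292624 and 21820560 reads were counted per library, and the totals of the 2 groups overlapped (exact permutation p = 0.286, two-sided). Of 53167 listed genes, 26531 had at least 1 count and 14415 passed the filter on low counts. The labels give no duration of stimulation, so the time point behind these values is not known here. They do not say whether the replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

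The cells carried transcripts of both mammary epithelial layers at similar levels in the 2 groups. The basal keratin Krt14 stood at 3528 ± 88.1 CPM (counts scaled to a common library total) in BGN and 3744 ± 358 CPM in Control, and Krt5 at 1479 ± 72.4 and 1548 ± 105 CPM (SD, n = 5 each, as for all values per group). The luminal keratins Krt8 and Krt18 reached 877 ± 26.2 and 567 ± 26.3 CPM in BGN, against 916 ± 45.5 and 599 ± 35.2 CPM in Control. Epcam, an epithelial adhesion molecule, was at 1119 ± 24.2 and 1136 ± 43.0 CPM, and Csn3, the kappa-casein gene, at 1113 ± 47.4 and 1123 ± 231 CPM. Markers of other cell types were scarce: the summed CPM per library lay between 18.3 and 22.5 for 13 myeloid markers, between 9.62 and 12.4 for 12 endothelial markers, between 1.11 and 2.42 for 12 lymphocyte markers, between 3.81 and 6.23 for 11 skeletal muscle markers and between 0.0987 and 0.433 for 7 red blood cell genes. None of these 5 sums passed a test between the groups (exact permutation tests, two-sided, unadjusted p = 0.833, 0.0952, 0.238, 0.262 and 0.437 in that order). Within the myeloid sum, Cd163 alone gave 17.4 ± 1.32 CPM in BGN and 17.2 ± 2.16 CPM in Control. Postn, listed here among fibroblast markers, was abundant at 2032 ± 223 CPM in BGN and 1729 ± 326 CPM in Control, while the other detected members of that list reached at most 235 ± 13.7 CPM in BGN (Col6a1). These abundant members were picked for their level after the values were seen. Fibroblast markers at lower levels included Pdgfra, Col1a1, Col3a1 and Col1a2. Their means over the 10 libraries were 38.7, 4.42, 0.438 and 0.316 CPM, scaled by library totals alone.

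**Figure D1:**
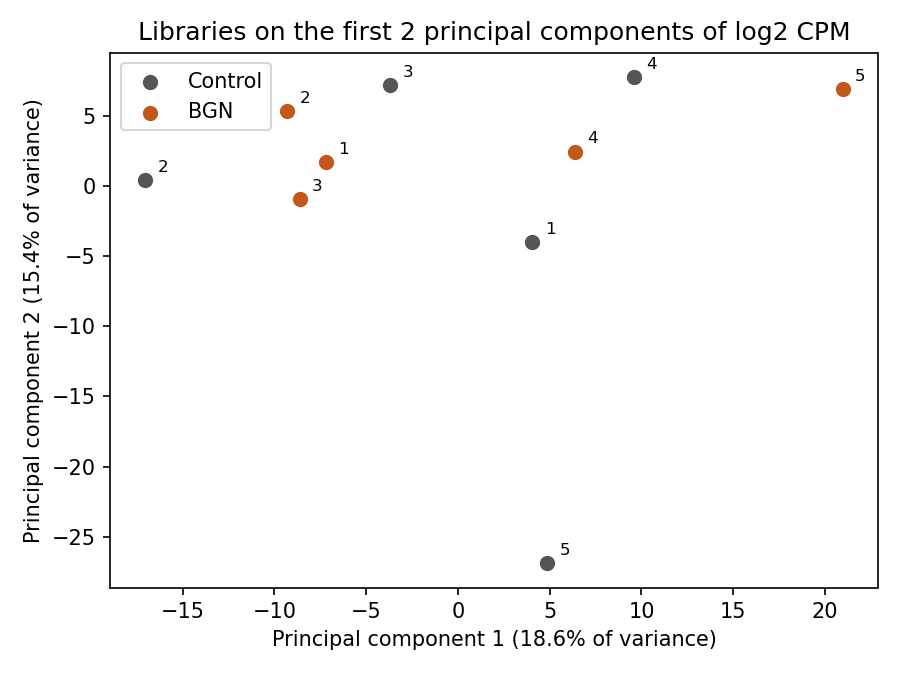
Principal components 1 and 2 of log2 CPM over the tested genes, with their share of the variance on the axes; each point is a library, coloured by group and marked with its replicate number. BGN and Control libraries are interspersed on component 1, and Control replicate 5 lies apart on component 2 at -26.9.

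The groups did not separate on the first 2 principal components, which held 18.6% and 15.4% of the variance (exact permutation p = 0.944 and 0.468, two-sided). Control replicate 5 stood apart on the second, at -26.9, and had 1.155% of its reads on mitochondrially encoded genes, against 1.80% to 2.27% in the other 9 libraries. BGN replicate 5 lay farthest out on the first component, at 21.0. The mitochondrial share was 2.2 ± 0.046% in BGN and 1.85 ± 0.431% in Control, and the share of ribosomal protein genes 3.81 ± 0.0576% and 4.05 ± 0.274% (exact permutation p = 0.0873 and 0.0714, both 0.262 after Benjamini-Hochberg adjustment over 6 library measures).

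No gene passed the test between BGN and Control: 0 were higher and 0 lower at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted, smallest adjusted p = 0.883). At an unadjusted p under 0.05 there were 694 genes, of which 351 had higher and 343 lower estimates in BGN, where 720.75 are expected with no effect. DESeq2 and limma-voom also called 0 genes, with 746 and 801 at an unadjusted p under 0.05. The CPM of the 2 groups did not overlap for 105 genes, or 0.728% of those tested, and chance gives 0.794%. The estimates were tight. The 95% interval of the fold change lay within 1.5-fold in either direction for 12237 genes (84.9%) and within 2-fold for 13948 (96.8%), and of the 11965 genes with a mean of at least 50 counts, 97.8% lay within 1.5-fold. Without the filter on low counts 3 genes passed, 1 with higher and 2 with lower values in BGN, among them Kctd12 and Oas3 (smallest adjusted p = 0.0145), while under the other settings tried the smallest adjusted p lay between 0.14 and 1. Oas3 lies outside the rule by which genes were named and was picked after its value was seen, at 2.01 ± 0.612 CPM in BGN and 3.64 ± 1.25 CPM in Control (log2 fold change -0.88).

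**Figure D2:**
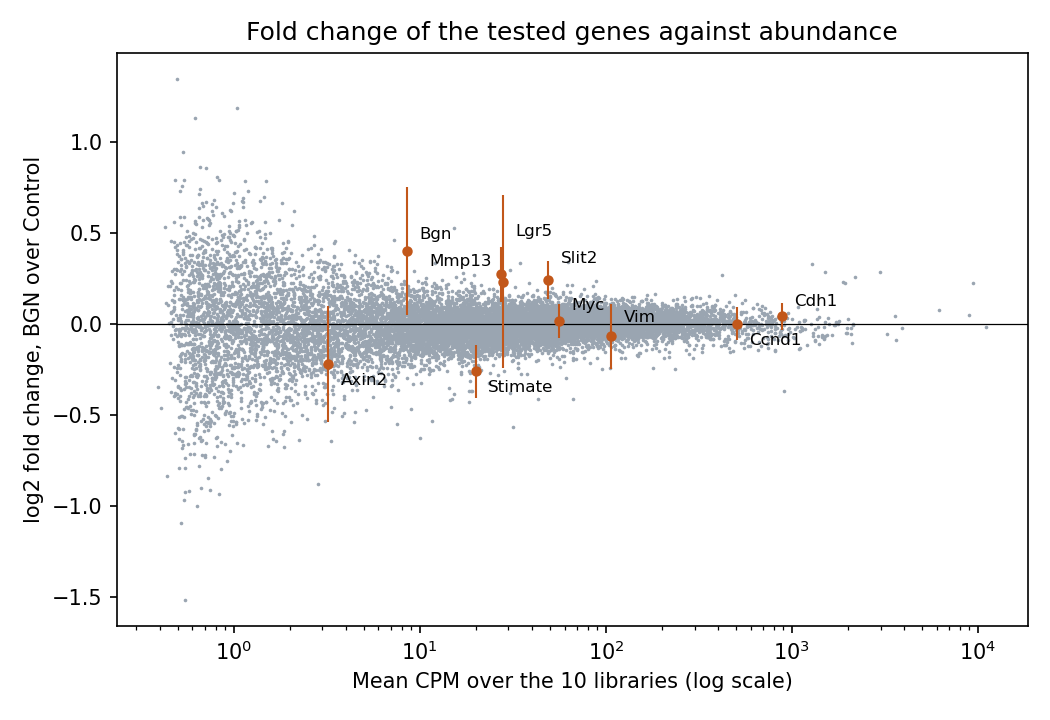
Log2 fold change of BGN over Control against mean CPM (log scale) for the 14415 tested genes, grey; orange points are named genes with their 95% interval. No gene passed the adjusted threshold, and the scatter widens toward low counts.

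The 10 genes with the smallest p among those with at least 50 counts on average had small fold changes, and none passed the adjusted threshold. Slit2, which encodes a secreted ligand of Robo receptors, came first, with 52.99 ± 1.70 CPM in BGN and 44.7 ± 2.87 CPM in Control, a log2 fold change of 0.24 ± 0.052 (SE) and an adjusted p of 0.883 by edgeR; all 5 BGN libraries lay above all 5 Control libraries. Epha4, an ephrin receptor, had a log2 fold change of 0.23, Apbb2 of 0.20, Kctd12 of 0.24, Naaladl2 of 0.22 and Celf2, an RNA-binding protein gene, of 0.16. The collagenase gene Mmp13 was at 29.8 ± 3.02 and 24.6 ± 2.16 CPM (log2 fold change 0.27), and Itgb8, an integrin beta subunit gene, at 195 ± 7.44 and 174 ± 11.5 CPM (0.17). Stimate and Nudt18 had the estimates below 0, at -0.26 and -0.25. The adjusted p of each of the last 9 genes was 0.945. Groups also did not overlap for Apbb2, Stimate and Nudt18. Since these genes were picked for a small p in the same comparison, a lack of overlap adds no support. The same holds for list members of smallest p named below.

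The transcript of biglycan itself was low. Bgn stood at 9.74 ± 1.71 CPM in BGN and 7.38 ± 1.88 CPM in Control, with a log2 fold change of 0.40 ± 0.16 (SE, 95% interval 0.053 to 0.75) and an adjusted p of 0.945 by edgeR. The groups overlapped. Among the 14 small leucine-rich proteoglycan genes 4 were tested, and 0 passed whether adjusted over the list alone or over all genes; Prelp was the most abundant, at 113 ± 3.48 and 105 ± 7.17 CPM (log2 fold change 0.099, and 0.065 without Control replicate 1). Of the reported biglycan receptors and co-receptors, 8 were tested, 6 with estimates above and 2 below 0. The innate immune receptor genes Tlr2 and Tlr4 were expressed at 104 ± 3.37 and 68.7 ± 2.88 CPM in BGN, against 104 ± 2.74 and 64.6 ± 3.88 CPM in Control. Their log2 fold changes were 0.0034 and 0.089, and the first turned to -0.00075 with library totals as the only scaling. The hyaluronan receptor gene Cd44, also a WNT target, was at 677 ± 17.9 and 627 ± 23.2 CPM (log2 fold change 0.11, adjusted p = 0.945 by edgeR). The list as a whole was not called (median log2 fold change 0.017, camera adjusted p = 0.394), and its smallest p adjusted over the list alone was 0.0649.

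**Figure D3:**
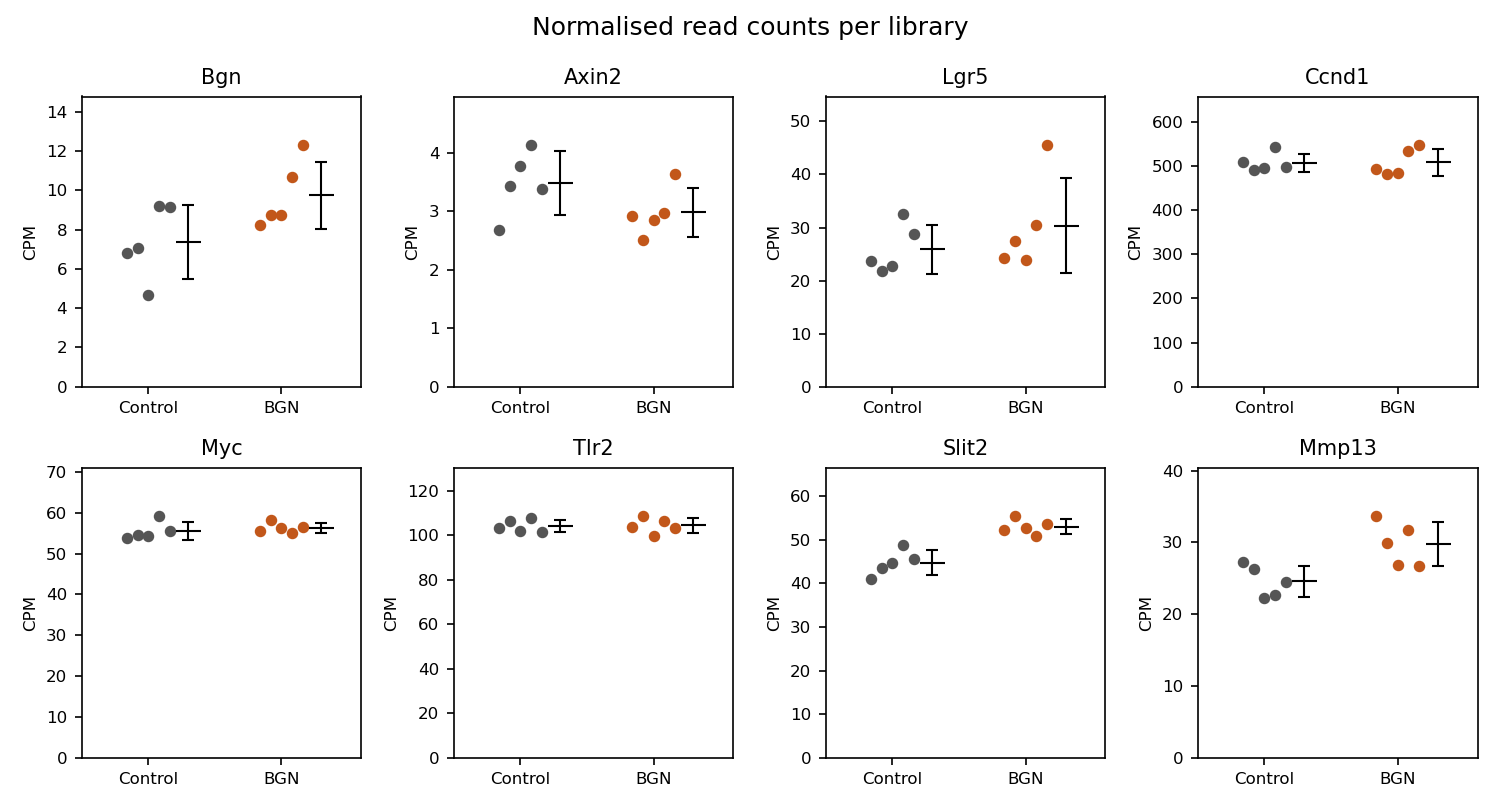
Normalised read counts (CPM, axes from 0) per library for 8 named genes; each point is a library and the bars give the mean ± SD of 5 libraries. The groups overlap for each gene shown except Slit2, and no difference passed the adjusted threshold.

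WNT/beta-catenin target genes did not move as a group. Of 28 listed targets 21 were tested: 12 had estimates above and 9 below 0, the median log2 fold change was 0.0031 and the mean -0.0013, and 0 passed whether adjusted over the list alone or over all genes. The list test gave a camera adjusted p of 0.730 in the direction up, and 0.914 with an estimated correlation. Without the filter on low counts, and without Control replicate 1, that direction turned to down (adjusted p = 0.877 and 0.873). Axin2, a feedback target induced in many tissues, was at 2.98 ± 0.412 CPM in BGN and 3.48 ± 0.543 CPM in Control, a log2 fold change of -0.22 with a 95% interval from -0.54 to 0.099. Lgr5, a stem cell marker and receptor for R-spondins, was at 30.3 ± 8.93 and 25.9 ± 4.60 CPM (0.23, interval -0.24 to 0.71, and 0.039 without BGN replicate 5). The cell cycle genes Ccnd1 and Myc had log2 fold changes of 0.0031 (interval -0.088 to 0.094) and 0.020 (-0.074 to 0.11; 0.0088 to 0.044 without single libraries), and the sign of Ccnd1 turned with library totals as the only scaling (-0.00084). Sox9 was at 0.072 (0.045 without Control replicate 1) and Nkd2 at 0.084 (0.035 without BGN replicate 5). Lef1 was not tested, with 0 counts in BGN and a mean of 0.0108 CPM in Control. The adjusted p of each tested target named here was at least 0.945 by edgeR. In counts simulated from these libraries, the same list raised 1.2-fold was called with the preset correlation. Simulated genes were independent of each other, and 0 of 38 lists were called there with no change. In the real libraries the same setting called a median of 5 lists over 100 splits into 5 and 5. Whether such a rise would be detected in these libraries therefore cannot be read from the simulation.

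Receptors were the WNT group with a call. Of 17 tested WNT receptors and co-receptors, 13 had estimates above and 4 below 0, and the list was called as higher in BGN by a small amount (median log2 fold change 0.035, camera adjusted p = 0.0232). The call was not kept with an estimated correlation (adjusted p = 0.532) or by fry (adjusted p = 0.159). This list had an estimated correlation of -0.0122, below the preset 0.01, and an unadjusted p of 0.014 by camera with that correlation and 0.00419 by fry. Its mean deviation per library was 0.032 ± 0.028 in BGN and -0.032 ± 0.048 in Control on the log2 scale (exact permutation p = 0.0397, two-sided, 0.754 adjusted over 38 lists), and the highest Control library was replicate 5, at 0.048. Fzd6 was at 181 ± 2.72 and 168 ± 6.26 CPM (log2 fold change 0.10), with no overlap between the groups, and Fzd5 at 21.7 ± 1.17 and 19.5 ± 2.05 CPM (0.15); both encode Frizzled receptors. Ror1 had a log2 fold change of 0.11 and Lgr6 of 0.099. No member passed adjusted over the list alone (smallest adjusted p = 0.250) or over all genes. The adjusted p of the list passed 0.05 without BGN replicate 3 (0.0811) or 5 (0.066), and without Control replicate 1 (0.116), 2 (0.0607) or 4 (0.071). It was 0.139 with each library's trend on transcript length and GC content removed. There the median difference of group mean log2 CPM stayed at 0.033 against 0.031 before. This removal was chosen after seeing the data.

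The remaining parts of the pathway were not called. Intracellular transducers numbered 26, with 16 above and 10 below 0 (median 0.014, camera adjusted p = 0.328). Ctnnb1, the beta-catenin gene, stood at 1740 ± 87.0 CPM in BGN and 1722 ± 89.7 CPM in Control; the transcription factor gene Tcf7l2 had a log2 fold change of 0.16 and Dvl1, a Dishevelled gene, of -0.13, neither passing. Only 8 of 19 WNT ligands were tested, 1 above and 7 below 0 (median -0.036, camera adjusted p = 0.684). Wnt5a was at 27.3 ± 1.34 and 25.7 ± 3.00 CPM, and Wnt10b at 4.73 ± 0.268 and 5.11 ± 0.632 CPM. Secreted antagonists split 3 above and 5 below 0 (camera adjusted p = 0.877), with Sostdc1 at 0.088 (0.058 without Control replicate 2) and Wif1 at 0.20, or 0.061 without BGN replicate 5. The planar polarity and calcium branch had 10 of 19 genes above 0 (camera adjusted p = 0.328); Vangl2 was at 0.11, with no overlap between the groups, and Nfatc1 at 0.17.

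Lists of adhesion, migration and matrix turnover were not called. In the integrin and migration list 20 of 29 genes lay above 0 (median 0.015, camera adjusted p = 0.328), and 1 passed adjusted over the list alone, Itgb8, but 0 over all genes. Itgav, whose product pairs with that of Itgb8, was at 336 ± 23.1 CPM in BGN and 305 ± 16.0 CPM in Control (log2 fold change 0.14). Matrix proteases and their inhibitors numbered 20, with 12 above 0 (median 0.017, camera adjusted p = 0.159). Of these, 2 passed adjusted over the list alone, Mmp13 and the protease inhibitor gene Timp3 (320 ± 21.8 and 288 ± 13.7 CPM, log2 fold change 0.15), and 0 over all genes. The mean deviation of this list was 0.043 ± 0.070 in BGN and -0.043 ± 0.043 in Control (exact permutation p = 0.0397, two-sided, 0.754 adjusted over 38 lists). Mesenchymal genes of epithelial-mesenchymal transition split 8 above and 6 below 0 (camera adjusted p = 0.821). Among them, Snai1, a repressor of Cdh1, was at 4.84 ± 0.388 and 6.39 ± 1.40 CPM (log2 fold change -0.40), Mmp3 at 5.24 ± 1.36 and 4.16 ± 0.337 CPM (0.34, and 0.23 without BGN replicate 1), and Vim at 104 ± 10.3 and 109 ± 12.1 CPM (-0.066, and -0.124 to -0.024 without single libraries). Epithelial junction genes split 10 and 9 (camera adjusted p = 0.877); the E-cadherin gene Cdh1 was at 895 ± 10.2 and 867 ± 26.2 CPM (0.045, and 0.027 without Control replicate 1), Crb3 had a log2 fold change of -0.17 and Cldn7 of -0.086. Basement membrane genes split 8 and 8 (camera adjusted p = 0.328).

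**Figure D4:**
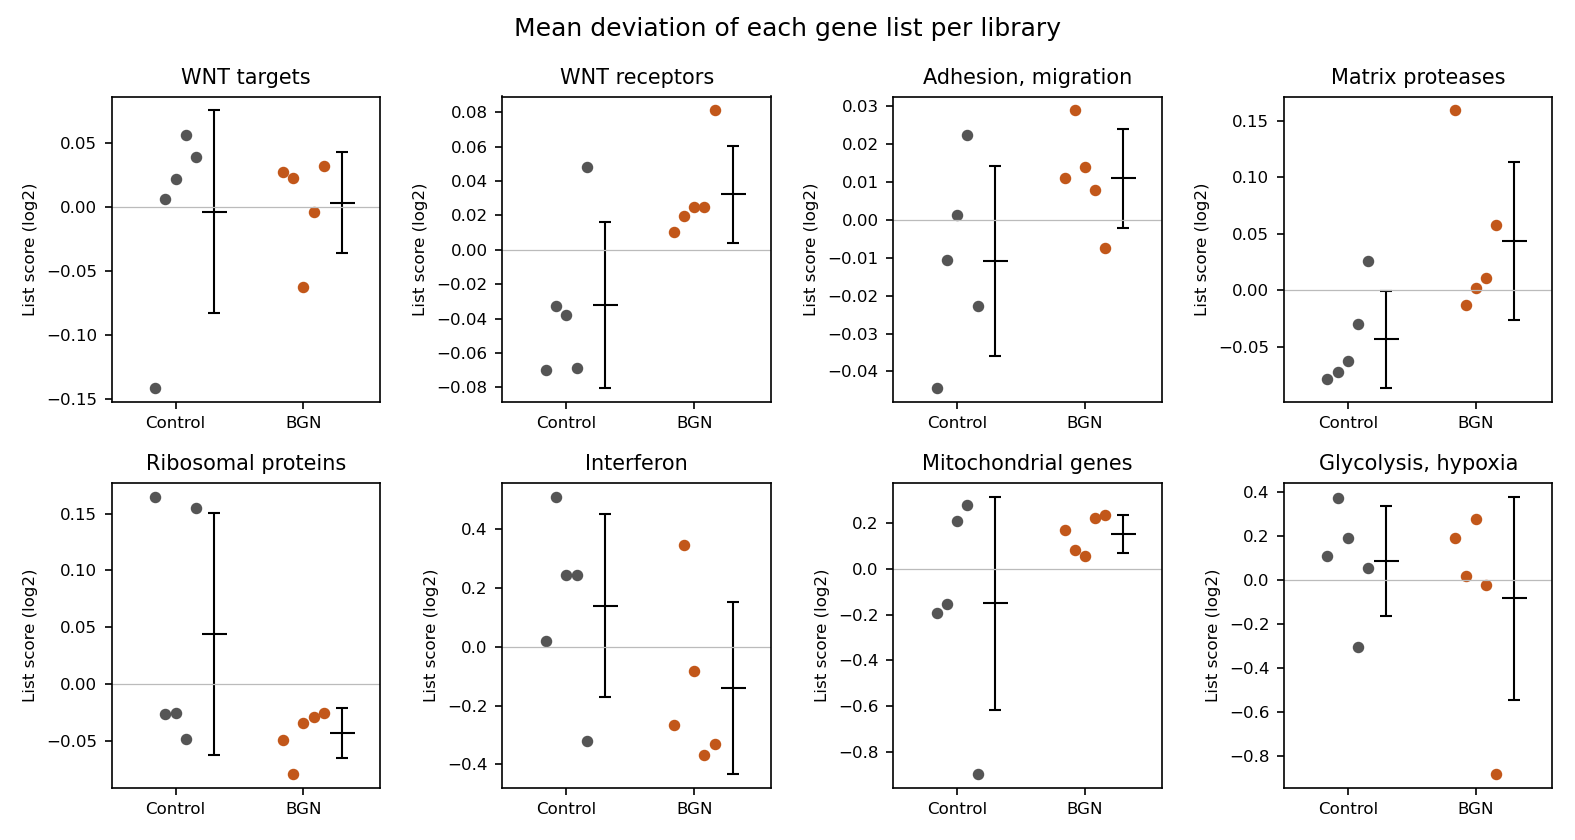
Mean deviation of each list's genes from their average over the 10 libraries (log2 scale, axes differ between panels); each point is a library and the bars give the mean ± SD of 5 libraries. Control replicates 1 and 5 carry the high ribosomal values, Control replicate 5 the low mitochondrial one at -0.90, and BGN replicate 5 the low glycolysis one at -0.88.

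Besides the WNT receptors, 5 lists were called with the preset correlation, and 0 of the 6 with an estimated one or by fry. Cytosolic ribosomal protein genes were lower in BGN by a small amount, with 77 of 78 below 0 (median log2 fold change -0.0855, camera adjusted p = 3.81e-15, adjusted p = 0.702 with an estimated correlation). Rpl38 was at 62.2 ± 1.34 and 71.3 ± 7.73 CPM and Rps24 at 769 ± 9.64 and 850 ± 66.1 CPM, both without overlap of the groups; many of these genes have near-identical pseudogenes, so their counts are uncertain. Nuclear respiratory chain genes had 77 of 91 below 0 (median -0.060, camera adjusted p = 4.42e-06, adjusted p = 0.775 with an estimated correlation). Their camera adjusted p was 0.0811 without Control replicate 1 and 0.107 with the length and GC trend removed. With that removal the median difference of group mean log2 CPM was -0.019 against -0.053 before. Ndufa7 and Ndufb3 had log2 fold changes of -0.16 and -0.17. The ribosomal deviations were highest in Control replicates 1 and 5, at 0.165 and 0.155, and between -0.080 and -0.026 in the other 8 libraries. All 13 mitochondrially encoded genes had estimates above 0 (median 0.26, camera adjusted p = 1.54e-05, adjusted p = 0.702 with an estimated correlation), mt-Nd4 at 1422 ± 61.5 and 1130 ± 299 CPM and mt-Co2 at 33.7 ± 3.18 and 27.4 ± 5.26 CPM; Control replicate 5 had the lowest deviation, -0.90.

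Interferon-stimulated genes were lower in BGN in 24 of 25 estimates (median log2 fold change -0.28, camera adjusted p = 3.26e-08, adjusted p = 0.702 with an estimated correlation). Gbp2, a guanylate-binding protein gene, was at 64.5 ± 5.95 CPM in BGN and 73.6 ± 8.92 CPM in Control (log2 fold change -0.19). Libraries of the 2 groups overlapped widely: the deviations ran from -0.37 to 0.35 in BGN and from -0.32 to 0.51 in Control (exact permutation p = 0.175, two-sided, 0.945 adjusted over 38 lists). The 20 glycolysis and hypoxia genes all lay below 0 (median -0.11, camera adjusted p = 0.0226, adjusted p = 0.914 with an estimated correlation), with Pkm at 2022 ± 186 and 2169 ± 163 CPM and Ldha at 1352 ± 164 and 1456 ± 110 CPM. BGN replicate 5 alone was at -0.88, and without it the direction turned and the call ended (adjusted p = 0.525). The call was also lost without Control replicate 1 (0.0811), 2 (0.252) or 3 (0.203), and with the length and GC trend removed (0.0526). With that removal the median difference of group mean log2 CPM was -0.123 against -0.135 before.

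No other list was called. Among markers of mammary lineages, the camera adjusted p was 0.328 for basal, 0.874 for luminal progenitor, 0.874 for hormone-sensing luminal, 0.877 for milk protein and 0.975 for squamous keratinisation genes, and for stromal types 0.237 for fibroblast and 0.720 for adipocyte markers. For signalling lists it was 0.328 for TGF-beta targets, 0.445 for Notch, 0.618 for YAP/TEAD targets, 0.662 for NF-kB and inflammatory genes, 0.684 for EGF, FGF and HGF family ligands and receptors, and 0.720 for BMP targets. Immediate early genes gave 0.684, with 1 member passing adjusted over the list alone. Cell cycle genes had 24 of 32 estimates below 0 (0.684), p53 targets gave 0.734, heat shock genes 0.720, the unfolded protein response 0.328, cholesterol synthesis 0.874, fatty acid synthesis 0.452 and histone genes 0.672. In the WNT target, epithelial junction, luminal progenitor, hormone-sensing luminal, milk protein, squamous, adipocyte and immediate early lists, the median, the mean and the direction of the test differed in sign. Leaving out BGN replicate 5 and Control replicate 5 together, chosen after seeing the data, raised the number of lists called with the preset correlation from 6 to 15, and leaving out Control replicate 1 lowered it to 3.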

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

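All tests of sequencing depth and of the treatment in this part, and the HIF values without libraries, were chosen after the results were seen; the other tests of explanations were written before their own result but after exploratory runs on these data. Within each group of 5 libraries, a library was singled out where its gap to the nearest other exceeded 0.71 of the range. Of 274 such groups examined 17 had one, where chance alone gives about 13.7, and 8 of the 17 were BGN replicate 5.

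In BGN replicate 5 the deviation of the glycolysis and hypoxia list was -0.88 (others -0.025 to 0.28), that of the WNT receptors 0.081 (0.010 to 0.025) and that of luminal progenitor markers -0.134 (0.016 to 0.069). The same library had Ldha at 1067 CPM (1365 to 1468), Lcn2 at 1835 CPM (2055 to 2141), Krt6a at 305 CPM (358 to 376), Tlr4 at 63.7 CPM (69.5 to 71.1) and Col6a2 at 232 CPM (187 to 200). Control replicate 5 stood apart with an epithelial junction deviation of 0.050 (-0.018 to 0.0017) and an NF-kB deviation of -0.110 (-0.0042 to 0.037). Control replicate 2 had 20658 genes with a count (19985 to 20126) and a histone deviation of -0.307 (0.061 to 0.168). Control replicate 4 had a biglycan receptor deviation of -0.051 (-0.0026 to 0.016) and Wif1 at 7.61 CPM (5.97 to 6.44). Control replicate 1 had a WNT target deviation of -0.141 (0.0065 to 0.056), BGN replicate 1 a mesenchymal one of 0.146 (-0.039 to -0.0024) and BGN replicate 3 an unfolded protein response one of 0.060 (-0.053 to -0.023).

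The glycolysis and hypoxia list formed an axis on which BGN replicate 5 was lowest and Control replicate 2 highest (0.37). A candidate explanation is a difference in oxygen or HIF activity between the cultures: 21 HIF target genes outside the list followed the deviation with a median r of 0.961 over the 10 libraries, above the highest of 10000 random lists of matched expression (0.499). The median r was 0.905 without BGN replicate 5 and 0.812 without that library and Control replicate 4 (highest random lists 0.379 and 0.439). Since the list itself holds HIF targets, this does not tell oxygen from another regulator of the same genes. Sequencing depth stays open, with a Pearson r of -0.366 (bootstrap 95% interval -0.852 to 0.827, permutation p = 0.314, Spearman's rho -0.0545, p = 0.892), which fell away to 0.064 without BGN replicate 5 and Control replicate 2 and so rests on those libraries. For the treatment the exact permutation p was 0.571, and the interval of the difference, -0.62 to 0.20, reaches past the SD within groups of 0.371, so an effect cannot be told apart from none with 5 libraries per group. How oxygen or cell density varied between the cultures was not analysed here.

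Ribosomal protein and respiratory chain genes were lower in BGN mainly against Control replicates 1 and 5. These 2 libraries also stood apart in their trends on transcript length and GC content: Control replicate 1 had a slope of -0.0614 per doubling of length (others -0.00683 to 0.0214) and Control replicate 5 one of 0.123 per 10% GC (others -0.0388 to 0.0157). After each library's trend on transcript length and GC content was removed, the median ribosomal difference of group mean log2 CPM went from -0.083 to -0.0429 (bootstrap 95% interval over genes -0.0566 to -0.0285), which spans a loss of 50% of its size. The ribosomal list was still called with the preset correlation (adjusted p = 9.87e-07), but with an estimated correlation it was not called even before the removal (adjusted p = 0.702). The respiratory chain median, over the 85 genes of known length, went from -0.053 (interval over genes -0.069 to -0.037) to -0.019 (-0.032 to -0.0017). These intervals over genes hold the libraries fixed, so they do not measure the spread between samples. The call of the respiratory chain ended after the removal (adjusted p = 0.107), and the cause was not tested. A trend on length and GC is therefore a candidate explanation for part of the pattern, and how large a part cannot be told apart from these values, since the genes of the list also move together (correlation 0.618). The treatment stays open as well: the exact permutation p was 0.111. The difference was -0.087 (bootstrap 95% interval over libraries -0.173 to -0.00395, just short of 0), larger than the SD within groups of 0.0769.

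The interferon list was lower in BGN on average, but 17 of 100 splits of the libraries gave a camera p as small as the real 1.71e-09 (smallest of the others 3.74e-51), so chance is not excluded. A contribution of RNA from myeloid cells was not decided: the summed myeloid CPM followed the deviation with r = 0.357 (bootstrap 95% interval -0.271 to 0.831, permutation p = 0.314, Spearman's rho 0.285, p = 0.426, and r = 0.18 without Control replicates 1 and 5), while Cd68 and Csf1r stood at 1.69 and 1.34 CPM in BGN and 1.62 and 1.19 CPM in Control. This explanation needs less myeloid RNA in BGN. The myeloid sum was not lower there, at 21.1 ± 0.800 CPM against 21.0 ± 1.79 CPM in Control (exact permutation p = 0.833, two-sided, unadjusted). These markers thus gave no sign of such a difference, but with this spread and low level they do not exclude it. Depth was not decided either, at r = -0.2 (interval -0.871 to 0.532, permutation p = 0.57, Spearman's rho -0.321, p = 0.369, and r = -0.508 without BGN replicate 5 and Control replicate 2). With the glycolysis relation these were 3 correlations, with adjusted p of 0.471, 0.57 and 0.471 for r and 0.639, 0.639 and 0.892 for rho. The treatment gave an exact permutation p of 0.175, with an interval of the difference from -0.59 to 0.070 against an SD within groups of 0.302, and stays open.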

How the results depend on the processing

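The alternatives that left out BGN replicate 5 with Control replicate 5, and that removed the trend on length and GC, were chosen after seeing the data. Under each setting but one, 0 genes were called; without the filter on low counts 3 were (1 higher, 2 lower), and the cause was not tested. The labels do not say whether shared replicate numbers pair the libraries, and the values do not settle it. Of 5 same-number correlations 1 was over 0.1, and 3 of 10 libraries correlated best with their own number. With the replicate block 0 genes and 6 lists were called, as without it. The smallest adjusted p over genes was 0.238 with the block and 0.883 without it, and 825 and 694 genes had an unadjusted p under 0.05. No scaling moved the median log2 fold change of all genes past -0.0083. The Bgn log2 fold change lay between 0.28 and 0.49 when single libraries were left out and stayed uncalled in each setting. Of lists, 0 were called with an estimated correlation and 0 by fry, 15 without BGN replicate 5 and Control replicate 5, 3 with the length and GC trend removed, and 3 to 9 without single libraries; those causes were not tested, except that the estimated correlation is larger than the preset one in 5 of the 6 called lists. With an estimated correlation the adjusted p was 0.532 for WNT receptors, 0.702 for interferon, ribosomal and mitochondrially encoded genes, 0.914 for glycolysis and 0.775 for the respiratory chain; by fry it was 0.159, 0.646 for those 3, 0.926 and 0.692. With the trend removed it was 0.139 for WNT receptors, 0.0526 for glycolysis and 0.107 for the respiratory chain. Over genes of known length the median difference of group mean log2 CPM in these lists, in the same order, went from 0.031 (bootstrap 95% interval over genes 0.0093 to 0.10) to 0.033 (-0.017 to 0.090), from -0.135 (-0.163 to -0.105) to -0.123 (-0.135 to -0.080) and from -0.053 (-0.069 to -0.037) to -0.019 (-0.032 to -0.0017). These intervals resample the genes of a list with the libraries held fixed, so they do not measure the spread between samples. Without single libraries the adjusted p ranged from 0.00976 to 0.116 for WNT receptors, 0.000132 to 0.525 for glycolysis and 6.12e-09 to 0.0811 for the respiratory chain. The other 3 lists stayed called with the preset correlation whichever single library was left out. Their camera adjusted p ranged from 3.99e-18 to 0.000459 for interferon, 4.45e-19 to 5.62e-07 for ribosomal and 2.12e-07 to 0.00234 for mitochondrially encoded genes. The glycolysis direction turned without BGN replicate 5 and without both libraries (0.551). The WNT target direction turned without the low-count filter (0.877) and without Control replicate 1, the adjusted p ranging from 0.487 to 0.988 without single libraries. Uncalled genes near 0 changed sign. Ccnd1 was at -0.00084 with library totals, -0.012 by limma-voom, -0.018 with a surrogate variable, -0.032 without both libraries, and -0.024 to 0.028 without single libraries. Tlr2 was at -0.00075 with library totals, -0.00085 without both libraries, and -0.010 to 0.019 without single libraries. No other gene given with a log2 fold change in the report changed sign. An interval reaching past 1.5-fold was found for 15.1% of tested genes. Low counts do not account for all of them, since abundant genes were included. For mt-Nd4, with a mean of 25153 counts, the log2 interval ran from -0.094 to 0.76.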

Other observations

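The samples were also split in other ways into 5 and 5. Of 126 possible splits 100 were drawn, the real one included, and all 100 gave at least the 0 genes of the real split, as any split must, so this count decides nothing about chance. Of the 100, 4 called any gene, the highest 172; these few may reflect a structure of the samples or arise with no effect. At an unadjusted p under 0.05 the real split gave 694 genes and 29 of 100 splits gave as many (highest other 2330). With the preset correlation the real split called 6 lists, as did or exceeded 36 of 100 splits (highest other 14, median 5). Chance is excluded for neither of these 2 counts.

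The WNT receptor list was matched by fewer splits. Its camera p of 0.00366 was reached by 1 of 100 splits, the real one, and the smallest p among the others was 0.00636. The exact permutation p of its mean deviation was 0.0397, two-sided. Taken alone, this list was thus seldom matched by a chance division of the libraries, which makes chance less likely but does not exclude it. It was singled out after its value was seen, from 38 lists, of which 2 had fewer than 5 of 100 splits as small (WNT receptors and matrix proteases, with 1 and 2), where 1.52 are expected, so over the 38 lists chance is not excluded. A slight rise of receptor transcripts such as Fzd6 with biglycan may therefore be real or a product of the number of lists, and its adjusted p of 0.754 by permutation, with 0.532 under an estimated correlation, leaves this open.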
